A study of Arabidopsis thaliana with 9 samples.

How the data were processed

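The series measured which inserts of an Arabidopsis cDNA library were carried by yeast colonies selected in a two-hybrid screen. Per the labels' protocols, plasmids were extracted from the selected yeast, the prey inserts were amplified by PCR and sheared to 200 to 300 bp, adaptors were ligated, and fragments with 29 bp of vector sequence were enriched by a further PCR before paired-end sequencing. The reads of a gene therefore come from the junction of vector and insert and were not divided by gene length. They count PCR copies of plasmids from colonies, and a read number is not a measure of binding strength. The submitters' processing notes name CASAVA, cutadapt, HISAT2 and the TAIR10 genome, with no role or order. How reads were assigned to genes, whether reads of similar genes were divided and what makes a read distinct are not given in the sources used here.

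The authors deposited 1 table of 10224 genes with 2 values for each of the 9 libraries, per the file headers a read count and a number of unique reads per gene, called distinct reads here. The deposited values are whole-number counts that were not normalized, and cells without a read hold a mark in place of 0, which was read as 0. The distinct-read column of SCAB1 replicate 3 was not used, because 10224 of its 10224 cells equal those of SCAB1 replicate 2. It gave 1429 genes more distinct reads than reads, against 0 in the other 8 libraries. Gene symbols came from the RefSeq table of assembly TAIR10.1, in which 10201 of the gene identifiers were found and 23 were not, and no coordinates were taken from it because the builds differ in name. Read totals were 1640114 to 3288437 per library with a median of 2110556. A distinct read stood for 45.9 to 137 reads in the 8 libraries where it could be used, so reads are not independent counts and their sampling error was not estimated. Read counts of libraries of 1 bait differed by a chi-square of 22.5 to 77.3 per degree of freedom over genes, so no library was a copy of another.

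Groups were the 3 baits named in the labels, and recovery time was taken from the labels. The tests had been planned with edgeR and DESeq2, but edgeR and DESeq2 were not used. A check of units did not accept columns with marks for empty cells as plain counts. With the marks read as 0 the values are counts, so the marks do not themselves rule out either test. The main test was limma-voom (limma 3.58.1 in R 4.3.3), which had been planned as an alternative, with recomputed TMM factors (30% of M values and 5% of A values trimmed) and an offset of 0.5 counts. Genes were tested if they had about 10 reads at the median library size in at least 3 libraries and 15 in all, which left 3811 genes with 98.6 to 99.8% of the reads. TMM factors ran from 0.438 in PKS5 replicate 2 to 2.40 in SOS2 replicate 1, with geometric means of 0.955 in PKS5, 0.855 in SCAB1 and 1.23 in SOS2. Each bait was compared with the mean of the other 2 on the log2 scale, in a fit of all 9 libraries with robust variance estimates. Recovery times were compared with bait as a block. P-values were adjusted by Benjamini and Hochberg over the genes tested, and an adjusted p under 0.05 was called. With library size alone, without genes above 5% of any library and with at least 100 reads, limma took the variance from all genes together (infinite prior degrees of freedom, against a median of 16 in the main test), so the smallest adjusted p-values in the ranges over alternatives rest on a spread that is not the gene's own. CPM values in the text are reads divided by the library total and scaled to a common total, without TMM, given as mean ± SD over 3 libraries.

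The test was tried on simulated data with the means and library sizes of these libraries, a dispersion of 0.217 and 200 changed genes. Of 50 genes changed 2-fold, 14% were recovered for PKS5, 10% for SCAB1 and 16% for SOS2, and of those changed 4-fold 70%, 72% and 78%. All genes changed 8-fold or 16-fold were recovered, and 6.58%, 2.08% and 9.26% of the calls were false. These runs had 3358 to 3565 genes in the fit. Simulated genes had 1 mean in all baits and 1 dispersion, except that the 200 were raised in 1 bait. In the data 27.7% to 40.7% of genes were called for a bait, in both directions, so these shares may not hold there. The number of genes with at least 10 reads, the effective number of genes and the share of the 10 highest genes were compared by exact permutation tests, over all 9 libraries and with baits permuted within recovery times, in Python 3.11.15 with scipy 1.17.1. Camera was run on gene lists with at least 3 tested members. Of 17 gene lists, 15 name 197 genes and 2 are all genes of the chloroplast and mitochondrial genomes, and 74 of the named genes were not analysed here.

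The genes named in the text were chosen by a rule. It took the 10 highest genes of each bait, the 10 highest called higher and the 3 called lower that did not overlap with the other baits, the 5 highest per direction for PKS5 against SOS2, the 4 highest and every called member of each list, the bait genes, the highest genes shared by all 9 libraries, and the 3 called genes per direction for each recovery time, of which there were none, and HISN5A and HISN5B, which were not analysed here. Some called list members are given only in counts, and some calls of a list member in a further bait are not given. Other genes named in the closing section were chosen after their values were seen. The settings also tried were library size alone, relative log expression factors, library size without genes above 5% of any library, no filter, at least 100 reads in 3 libraries, variance estimates that are not robust, recovery time as a replicate block, no bait block or recovery time as a number for the recovery contrasts, an estimated correlation in camera, overlaps of the 20 and 200 highest genes, and leaving out each library. Alternatives for the pools of preys were thinning to 1640114 reads, detection at 1 and 100 reads, and shares of the 1 and 20 highest genes. The gene lists, the rule for named genes, the tests as first planned and these settings were fixed before the data were examined. Limma-trend, distinct reads, the libraries at 0 h left out and a fold change above 2 were chosen after seeing the data.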

Results

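Prey inserts recovered from a yeast two-hybrid screen of an Arabidopsis cDNA library were counted by sequencing in 9 libraries. In such a screen a bait protein is fused to one part of a split transcription factor and library proteins, the preys, to the other, and yeast in which the parts are brought together make the HIS3 enzyme and grow without histidine. The baits were PKS5 and SOS2, protein kinases of the family that works with calcineurin B-like calcium sensors, and SCAB1, a plant protein that binds and bundles actin filaments. Each bait had 3 libraries, 1 each at recovery times of 0, 2 and 4 h, numbered 1, 2 and 3 in that order, and each was made from more than 3000 colonies grown on medium without tryptophan, leucine and histidine with 1 mM 3-AT, an inhibitor of the HIS3 enzyme. A library held 1640114 to 3288437 reads, so that 3 reads, the most that a count of 0 allows, were 0.912 to 1.83 CPM (reads scaled to a common library total), a limit for counting error only since PCR copies are not independent molecules. No unselected library is labelled, so the libraries of the other 2 baits served as the background. The 3 libraries of a bait differ in recovery time and are not said to come from separate cultures, and p-values therefore measure the spread between these libraries.

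Libraries of one bait held largely the same leading preys. The gene with the most reads was AT1G61170 in PKS5, at 279448 ± 41256 CPM (SD, n = 3), GAPC2, a cytosolic glyceraldehyde-3-phosphate dehydrogenase, in SCAB1, at 77663 ± 3518 CPM, and MEE14 in SOS2, at 231447 ± 56294 CPM. Pairs of libraries of the same bait shared 44.1 of their 50 highest genes on average, with a range of 43 to 47 over 9 pairs. Pairs of different baits shared 14.9, with a range of 9 to 19 over 27 pairs, and these ranges did not overlap. Across the 3811 tested genes, which are not independent replicates, the median Spearman rho was 0.902 for the same bait and 0.514 for different baits. Only 4 genes were among the 50 highest of all 9 libraries, namely AT1G61170, AT1G70790, AT3G47490 and FBA5, a fructose-bisphosphate aldolase. Their levels still differed between baits, with AT1G70790, a C2-domain protein, at 123601 ± 9935 CPM in PKS5, 38201 ± 3649 in SCAB1 and 4747 ± 406 in SOS2. FBA5 stood at 2466 ± 701, 15837 ± 1872 and 11750.1 ± 2472 CPM. The F test of limma-voom over the 3 baits passed for 1717 of the 3811 genes at an adjusted p under 0.05.

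**Figure D1:**
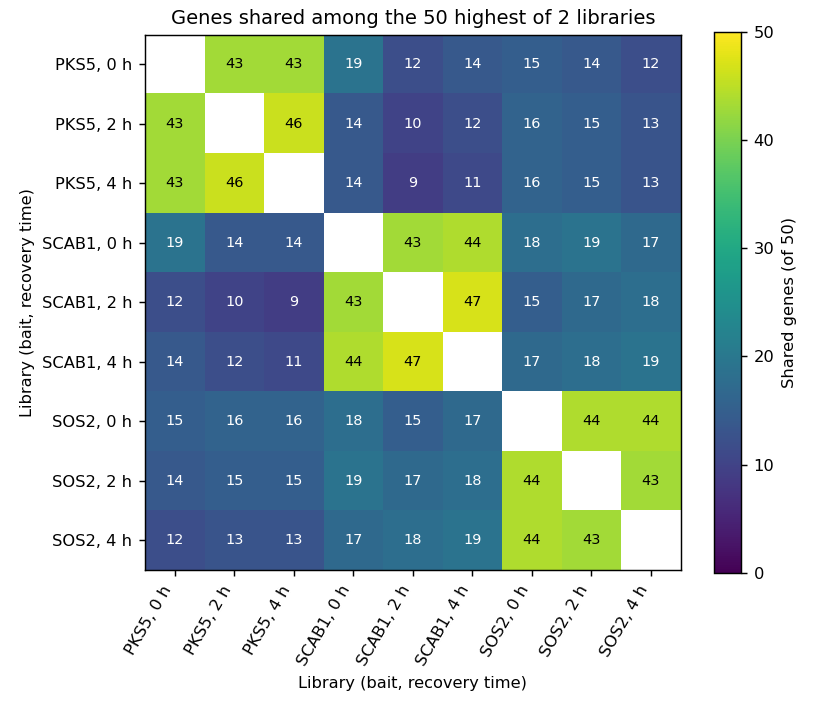
The grid gives, for each pair of the 9 libraries (rows and columns, by bait and recovery time in h), the number of genes that are among the 50 highest of both, on a colour scale from 0 to 50. Pairs of the same bait share 43 to 47 genes and pairs of different baits 9 to 19.

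Which preys were recovered more with PKS5 than with the other baits was asked first. The leading gene was AT1G61170 (log2 difference 4.84, SE 0.72, adjusted p = 1.31e-05 by limma-voom). AT1G70790 and AT5G37740, also among the leading genes, encode C2-domain proteins, which bind membrane lipids in a calcium-dependent way. Of these, AT1G70790 stood 3.26 log2 units above the mean of the other baits (adjusted p = 0.00093). AT5G37740 reached 43706 ± 2549.7 CPM against 52.5 ± 17.3 in SCAB1 and 7882 ± 2958 in SOS2 (adjusted p = 3.29e-07). AT5G47710 had 26392 ± 3848 CPM against 12.8 and 57.0 (log2 difference 10.16, SE 0.68, adjusted p = 9.88e-11). PGM3, a cytosolic phosphoglucomutase, had 54975 ± 10408 CPM against 23.4 ± 9.68 and 1575 ± 585 (log2 difference 8.31, SE 0.73, adjusted p = 5.73e-09). AT1G01730 was higher by 5.99 log2 units, and emb1507, an RNA helicase of the spliceosome, by 9.19, with 21477 ± 3327 CPM against 7.50 ± 3.85 and 285 ± 92.8. AT3G47490 and MYB3, a transcription factor of phenylpropanoid metabolism, were higher by 2.55 and 1.99. The call of AT3G47490 was lost without PKS5 replicate 2 (adjusted p = 0.0837, range over alternatives 2.31e-58 to 0.0837). The call of MYB3 (adjusted p = 0.0324, range 1.15e-30 to 0.228) was lost with relative log expression factors and without any 1 of PKS5 replicates 2 and 3, SCAB1 replicates 1 and 3 and SOS2 replicates 1 and 2.

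Among the fixed gene lists, partners of PKS5 named in the literature had 2 tested members, and 1 was called. This was J3, a DnaJ cochaperone, at 892 ± 489 CPM against 11.3 ± 3.57 and 11.9 ± 9.22 (log2 difference 6.48, SE 0.45, adjusted p = 1.58e-10), while its close relative J2 stood at 17.2 ± 9.85, 17.0 ± 7.56 and 18.9 ± 15.6 CPM. The other tested member, the proton pump AHA2, had 15.4 ± 7.08 CPM in PKS5 (adjusted p = 0.824). In SOS2 AHA2 was called higher by limma-voom, at 33.4 ± 25.7 CPM (adjusted p = 0.0405, range 0.0398 to 0.446), a call lost under 14 of 18 alternatives. Of the 2 tested clade A PP2C phosphatases, which act in abscisic acid signalling, PP2CA was higher in PKS5, at 119 ± 21.4 CPM against 5.12 ± 2.24 and 9.66 ± 6.44 (adjusted p = 1.75e-08), and ABI1 was not called (adjusted p = 0.942). Of 6 tested ubiquitin and SUMO genes, UBQ11 and UBQ3 were higher, at 16722 ± 2739 and 4756 ± 831 CPM, against 355 and 250.3 in SCAB1 and 708 and 121 in SOS2. Polyubiquitin genes are near-identical in sequence and how reads were divided between them is not given in the sources used here, so which copy was recovered is uncertain. The actin-depolymerising factor ADF4 had 603 ± 216 CPM against 5.22 ± 2.84 and 6.89 ± 6.65 (adjusted p = 2.68e-11), and it was the 1 member called higher of 9 tested actin-binding proteins. The proteasome subunit PBG1 had 75.8 ± 38.8 CPM against 6.38 ± 3.48 and 11.5 ± 8.75 (adjusted p = 5.57e-08), and 4 other proteasome genes of 16 tested were called lower in PKS5. The contrast averages the other baits on the log scale, and these 4 genes were highest in SOS2. PAD1, PBC1, PAE2 and PAG1 had 5.87, 8.36, 16.6 and 21.3 CPM in PKS5, against 3.85, 5.34, 14.3 and 22.8 in SCAB1. Of these the call of PAD1 held under each alternative run for it (18 of 19). Those of PAE2 and PAG1 were lost for library size alone (adjusted p = 0.176, range 0.00271 to 0.456, and 0.14, range 0.00321 to 0.432), with at least 100 reads, and without SCAB1 replicate 1 (PAE2, adjusted p = 0.0605) or PKS5 replicate 2 (PAG1, adjusted p = 0.0789). That of PBC1 was lost without genes above 5% of any library (adjusted p = 0.179, range 0.000154 to 0.655) and turned to a log2 difference of 0.22 with distinct reads. Of 4 tested actins, ACT8 was higher (adjusted p = 0.000637, lost with distinct reads at adjusted p = 0.339, range 4.6e-12 to 0.339) and the others were lower, with the call of ACT2 lost with distinct reads (adjusted p = 0.143) and without genes above 5% of any library (adjusted p = 0.172, range 0.00013 to 0.172). By the same averaging, ACT8 had 403 CPM in PKS5, 24.7 in SCAB1 and 422 in SOS2, and ACT2 had 36.8, 19.5 and 866. Of the highest preys of the other baits, GAPC2, GAPC1 and AT4G26860 had log2 differences of -6.97, -6.78 and -5.36 in PKS5 and were called lower.

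By limma-voom, 1054 of 3811 genes passed an adjusted p under 0.05 for PKS5 against the mean of the other baits, 229 higher and 825 lower. Of those higher, 104 had a mean of at least 100 CPM in PKS5. Of all 3811 tested genes, called or not, 119 (3.12%) had a higher CPM in each PKS5 library than in every library of the other baits and 193 (5.06%) a lower one. Chance gives each arrangement in 1.19% of unselected genes. A gene could reach the filter for testing through the 3 libraries of 1 bait alone, which raises the higher share. Such shares therefore do not test an effect of bait, here and below. The count depended on the scaling, with 679 genes (145 higher) for library size alone and 575 genes (226 higher, 39.3% against 21.7%) for library size without genes above 5% of any library. With distinct reads in place of all reads, in the 8 libraries where that column could be used, 205 genes passed and 95 of them were higher.

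**Figure D2:**
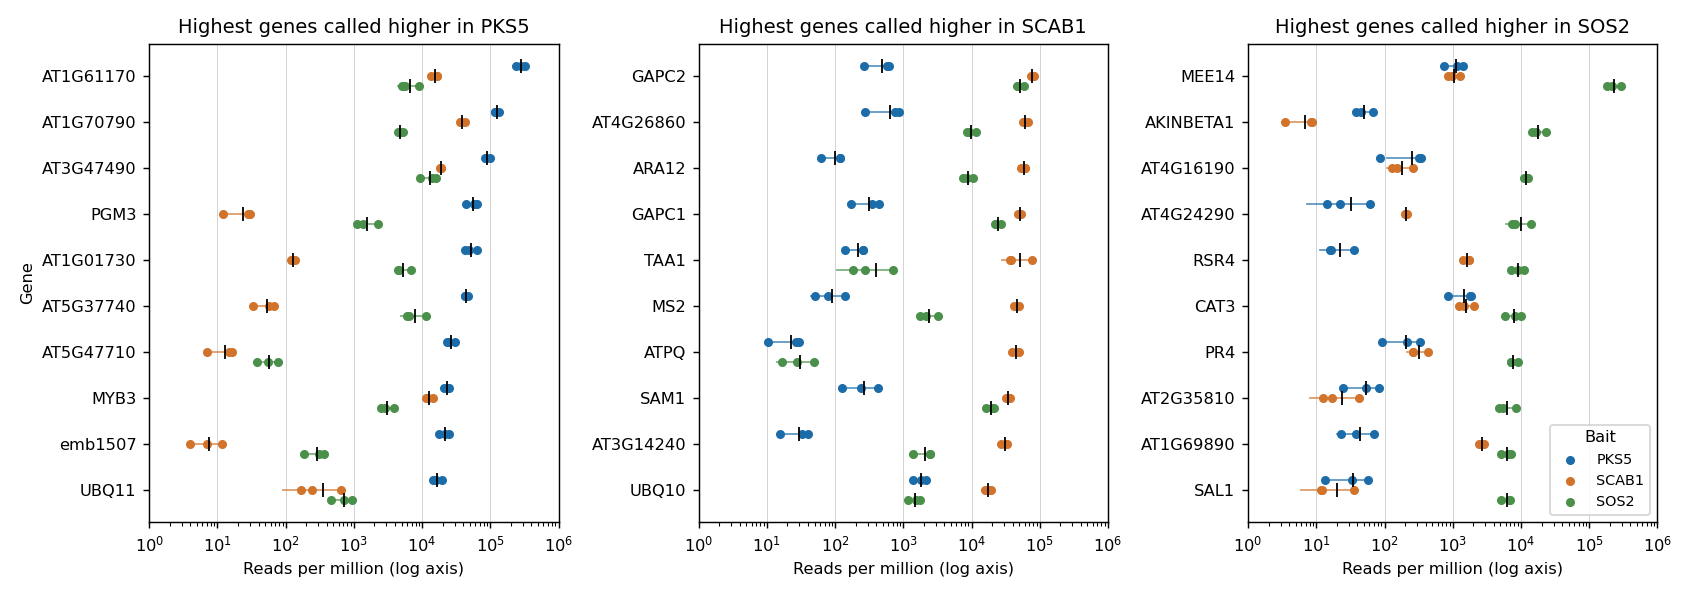
Each panel shows the 10 genes with the highest mean CPM among those called higher in 1 bait and higher in each of its libraries than in any other library (horizontal log axis, CPM). Points are libraries (3 per bait), black ticks are means and lines are the mean ± SD. In each panel the points of the named bait lie to the right of all others, as with MEE14 in SOS2 at 231447 CPM against 1097 in PKS5 and 1027 in SCAB1.

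With SCAB1 as bait the question was the same. ATPQ, a subunit of the mitochondrial ATP synthase, had 44856 ± 5566 CPM against 22.3 ± 10.5 in PKS5 and 31.0 ± 16.7 in SOS2 (log2 difference 11.21, SE 0.61, adjusted p = 8.92e-12 by limma-voom). TAA1, an aminotransferase of auxin synthesis, had 50515 ± 22950.1 CPM against 218 ± 68.7 and 392 ± 284 (adjusted p = 4.81e-08). MS2, a methionine synthase, was higher by 7.02 log2 units, AT3G14240 by 7.34, ARA12, a subtilisin-like protease, by 6.27, and AT4G26860 by 5.01, at 61694 ± 5278 CPM. GAPC2, GAPC1 and SAM1, an S-adenosylmethionine synthetase, were also called, by 4.34, 4.57 and 4.37, but the contrast averages the other baits on the log scale and these 3 genes were high in SOS2 too, at 50809 ± 6459.6, 24143 ± 2612 and 19150.3 ± 2658 CPM. GAPC1 and GAPC2 are close copies, so the division of reads between them is uncertain. PGM3, AT1G01730 and AT5G37740 were the leading genes called lower, and the mean CPM of PGM3 was 23.4 ± 9.68 in SCAB1.

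Of the 4 tested actins, ACT11 was higher in SCAB1, at 672 ± 65.9 CPM against 5.95 ± 3.76 and 8.15 ± 5.60 (log2 difference 7.17, SE 0.42, adjusted p = 9.17e-12), and ACT8 and ACT2 were lower, with adjusted p = 5.19e-08 and 5.3e-07, the latter a call lost with distinct reads (adjusted p = 0.126, range 2.24e-09 to 0.126). ACT7 had 227 ± 19.7 CPM and was not called (adjusted p = 0.762). Actins are close in sequence, so the division of reads among them is uncertain. Of 9 tested actin-binding proteins, 1 was higher and 3 were lower, and the 1 higher was SCAB1 itself, the bait gene, at 57.5 ± 22.8 CPM against 0.160 ± 0.276 and 1.69 ± 1.25. The SCAB1 gene reached the filter only through its own libraries, the highest level elsewhere being 2.73 CPM, so it was untested without any 1 of them. The 3 lower were ADF4, PRF2 and PRF3, and each call was lost with distinct reads (adjusted p = 0.306, range 7.11e-08 to 0.306, 0.877, range 0.00431 to 0.877, and 0.676, range 0.00465 to 0.676), those of PRF2 and PRF3 also for library size alone and with no filter. UBQ10 was the ubiquitin gene called higher, at 17621 ± 1869.6 CPM against 1792 ± 402 and 1485 ± 290.0 (adjusted p = 3.91e-05). ELC, an endosomal sorting protein, had 247 ± 73.1 CPM against 2.98 ± 1.51 and 21.0 ± 9.55 (adjusted p = 5.24e-09), although it was listed as a literature partner of SOS2. Of the COP9 signalosome only CSN6A was tested, at 14.2 ± 11.4 CPM in SCAB1, and its call (adjusted p = 0.015) was lost under 7 alternatives, among them library size alone (adjusted p = 0.115, range 0.00235 to 0.118) and leaving out SCAB1 replicate 1 or 3 or SOS2 replicate 1 or 2. In all, 1342 of 3811 genes passed, 552 higher and 790 lower, and 958 without SCAB1 replicate 1, 513 higher and 445 lower. Of all tested genes, called or not, 288 (7.56%) had a higher CPM in each SCAB1 library than in any other library and 118 (3.10%) a lower one, against 1.19% each by chance in unselected genes. The count was 830 for library size alone (333 higher and 497 lower), 890 without the libraries at 0 h (482 higher and 408 lower) and 220 with distinct reads.

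The preys of SOS2 were compared in the same way. MEE14 had 231447 ± 56294 CPM against 1097 ± 346 in PKS5 and 1027 ± 229.6 in SCAB1 (log2 difference 7.29, SE 0.63, adjusted p = 2.24e-09 by limma-voom). AKINBETA1, a regulatory subunit of the SnRK1 energy-sensing kinase, had 18011 ± 4665 CPM against 50.1 ± 15.2 and 6.84 ± 2.90 (log2 difference 9.65, SE 0.64, adjusted p = 1.24e-10). AT4G16190, a cysteine protease, was higher by 5.57 log2 units, AT4G24290 by 6.57, RSR4, an enzyme of vitamin B6 synthesis, by 5.21, and PR4, a pathogenesis-related protein, by 4.61. SAL1, a nucleotide phosphatase, had 6231 ± 929 CPM against 34.9 ± 22.0 and 19.9 ± 13.9 (adjusted p = 1.24e-10), and AT2G35810 and AT1G69890 had 6239 ± 2002 and 6231 ± 1085 CPM. GAPC2, GAPC1, SAM1 and AT1G33810 were high in SOS2 and SCAB1, and AT1G33810 had 15746 ± 3828, 22080.0 ± 2646 and, in PKS5, 96.9 ± 48.0 CPM. AT1G61170, AT1G70790 and AT3G47490 were the leading genes called lower, with log2 differences of -3.75, -4.24 and -2.07. The call of AT3G47490 was lost without SOS2 replicate 1 (adjusted p = 0.0931), without SOS2 replicate 2 (adjusted p = 0.058) and with distinct reads (adjusted p = 0.319), in a range of 6.52e-21 to 0.319.

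Of 7 tested literature partners of SOS2, 4 were higher in its libraries and 1 was lower. CAT3, a catalase, had 8009 ± 2092 CPM against 1479 ± 553 and 1586 ± 444 (log2 difference 1.99, SE 0.55, adjusted p = 0.0057), a call lost without SOS2 replicate 3 (adjusted p = 0.139) and with distinct reads (adjusted p = 0.956), in a range of 2.83e-13 to 0.956. CAT2, BIN2 and VAB3 were the others, at 26.1 ± 16.9, 17.8 ± 10.4 and 22.3 ± 15.4 CPM, and the calls of CAT2 and VAB3 were lost for library size without genes above 5% of any library (adjusted p = 0.0596, range 0.000525 to 0.0596, and 0.105, range 0.000931 to 0.167). The call of VAB3 was also lost without SCAB1 replicate 1 (adjusted p = 0.083). VAB2 was lower (adjusted p = 0.0165), a call lost for library size alone (adjusted p = 0.565, range 0.00408 to 0.565). Of the 10 calcineurin B-like sensors, which activate this kinase family in plants, 7 had any read and none reached the filter for testing. Their highest level in any library was 5.01 CPM, for CBL10 in SOS2 replicate 1, and SOS3, a literature partner of SOS2, was at 0 in 8 libraries and below the level that a count of 0 allows in the other. Of 7 tested CIPK kinases, 3 were higher, namely CIPK15, CIPK9 and CIPK7, and 2 lower, namely CIPK4 and PKS5. The calls of the 3 higher held under each alternative run for them. Of 19 alternatives, 18 tested CIPK15, 17 CIPK7 and 13 CIPK9. CIPK9 reached the filter only through its SOS2 libraries, the highest level elsewhere being 3.83 CPM, so it was untested without any 1 of them. CIPK4 lost its call for library size alone (adjusted p = 0.152, range 0.000223 to 0.152). The call of the PKS5 gene was lost without PKS5 replicate 2 (adjusted p = 0.0664), without SOS2 replicate 1 (adjusted p = 0.112) or 2 (adjusted p = 0.169) and with distinct reads, where it turned (log2 difference 0.10, adjusted p = 0.749), in a range of 1.22e-08 to 0.749. CIPK15 had 159.7 ± 75.1 CPM against 3.05 ± 2.79 and 3.43 ± 3.61 (adjusted p = 8.02e-08) and CIPK9 had 44.3 ± 17.5 against 2.40 ± 1.42 in PKS5 (adjusted p = 3.94e-07). Of 16 tested genes of the 20S proteasome, 4 were higher and 1, PBG1, was lower, a call lost for library size alone (adjusted p = 0.387, range 5.01e-05 to 0.387). PBG1 stood at 11.5 CPM in SOS2, against 75.8 in PKS5 and 6.38 in SCAB1. PAD1 had 333 ± 93.2 CPM against 5.87 ± 5.51 and 3.85 ± 1.02 (adjusted p = 8.4e-10), PBC1 had 269 ± 70.6, PAE2 139 ± 54.0 and PAG1 90.9 ± 12.9. Of 4 tested actins, ACT7, ACT2 and ACT8 were higher, with ACT7 at 5196 ± 1136 CPM against 15.9 ± 11.9 and 227 ± 19.7 (adjusted p = 9.11e-09). The call of ACT8, at 422 ± 114 CPM in SOS2 and 403 ± 196 in PKS5, was lost without SOS2 replicate 3 (adjusted p = 0.0976, range 0.000174 to 0.0976).

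In all, 1552 of 3811 genes passed for SOS2, 1033 higher and 519 lower. The higher and lower genes numbered 649 and 654 without SOS2 replicate 3, and 684 and 502 without SOS2 replicate 2. Of all tested genes, called or not, 799 (21.0%) had a higher CPM in each SOS2 library than in any other library and 34 (0.892%) a lower one, against 1.19% each by chance in unselected genes. CPM carries no TMM, and by library size alone the median log2 difference of all genes was 0.565 for SOS2, -0.504 for SCAB1 and -0.263 for PKS5 (0.157, -0.204 and -0.139 with TMM), so such counts include a general shift. With at least 100 reads required in 3 libraries the count was 992, of which 487 were higher, and with distinct reads it was 316. The share called higher rose from 66.6% to 85.0% for library size alone. PKS5 and SOS2, being related kinases, were also compared directly, and 1217 genes passed, 275 higher in PKS5 and 942 higher in SOS2. These were 419 and 586 without SOS2 replicate 3, 443 and 826 without SCAB1 replicate 1, 414 and 485 with at least 100 reads, and 129 and 787 for library size alone. AT1G61170, AT1G70790, AT3G47490, PGM3 and AT1G01730 led on the PKS5 side, and PGM3 had a log2 difference of 5.46, SE 0.82, adjusted p = 9e-06. MEE14, GAPC2, GAPC1, SAM1 and AKINBETA1 led on the SOS2 side, and AKINBETA1 had a log2 difference of -8.19, SE 0.66, adjusted p = 1.75e-09. With distinct reads 303 genes passed, 123 of them higher in PKS5.

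The bait genes themselves were read in the prey libraries at unequal levels. PKS5 had 1747 ± 162 CPM in its own libraries, 1195 ± 215 in SCAB1 and 684 ± 251 in SOS2, so that it was present with every bait, and the difference of its own libraries from the others did not pass (adjusted p = 0.187). SCAB1 was called in its own libraries as given above. SOS2 stood at 3.64 ± 2.69 CPM in its own libraries, was at 0 in all 3 SCAB1 libraries, and was not tested.

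No list passed a test as a whole. Camera with its preset correlation of 0.01 was run on the 10 lists with at least 3 tested members for each bait, and 0 of 30 pairs of list and bait passed. The smallest adjusted p was 0.251, for ubiquitin and SUMO genes in SOS2 (0 called higher and 3 lower of 6 tested), and the smallest adjusted p was 0.944 with an estimated correlation. The signs of the median, the mean and the test differed for actin-binding proteins in all 3 baits, for 14-3-3 proteins and mitochondrial genes in PKS5, for the proteasome in PKS5 and SOS2, and for actins, chaperones and SOS2 partners in SCAB1. Counts adjusted over the list alone were those over all genes except in these cases. Higher genes numbered 4 for CIPK kinases in SOS2 (3 over all genes) and 2 for 14-3-3 proteins, actin-binding proteins and ubiquitin and SUMO genes in SCAB1 (1 each). Lower genes numbered 1 for ubiquitin and SUMO genes in PKS5 and the COP9 signalosome in SOS2 (0 each) and 0 for 14-3-3 proteins in PKS5 and mitochondrial genes in SOS2 (1 each). The phosphoserine-binding 14-3-3 proteins had 8 tested members, of which 0 were higher and 1 lower in PKS5, 1 and 4 in SCAB1 and 3 and 0 in SOS2. None of these calls held under each alternative run for it. The calls of GRF5 in PKS5 (range of adjusted p 0.0251 to 0.607), GRF1 and GRF2 in SCAB1 (0.0112 to 0.43 and 0.00594 to 0.201) and GRF2 in SOS2 (0.0289 to 0.367) were each lost without any 1 of 5, 5, 5 and 8 libraries. The highest, GRF6, had 138 ± 52.6 CPM in SOS2, where its call (adjusted p = 0.00203) was lost without SOS2 replicate 3 (adjusted p = 0.0579, range 0.00172 to 0.646). Of the 4 tested TCP transcription factors and 4 tested chaperones, none was called except J3. The TCP factor TCP21 stood at 228 ± 54.3, 235 ± 98.4 and 226 ± 88.8 CPM. Of genes listed for the organelle genomes, ATMG00030 was the highest, at 811 ± 274 CPM in PKS5, 3768 ± 947 in SCAB1 and 3368 ± 1836 in SOS2. It was lower in PKS5 (adjusted p = 0.00498, lost with distinct reads at adjusted p = 0.41, range 1.71e-06 to 0.41). In SCAB1 it was called higher by limma-voom (adjusted p = 0.0375), a call lost under 9 of 19 alternatives. ATMG01200 was called lower in SOS2 (adjusted p = 0.0382), a call lost under 7 of 17. The 1 tested chloroplast gene, ATCG00440, was not called in any bait. Of the lists of 10 genes of histidine biosynthesis and 21 of photosynthesis, 0 genes were tested, and these lists were not analysed here.

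The share of reads in few preys had its highest mean with PKS5. Its 10 highest genes took 73.2 ± 7.14% of the reads (SD, n = 3), against 49.3 ± 3.53% in SCAB1 and 40.8 ± 6.84% in SOS2. The effective number of genes, the exponential of the Shannon entropy, was 37.1 ± 15.5 in PKS5, 101 ± 33.0 in SCAB1 and 174 ± 96.1 in SOS2. For each measure PKS5 differed from the other baits with p = 0.0238 in a two-sided exact permutation test, the smallest value that 3 against 6 libraries allow, and with p = 0.107 after Benjamini-Hochberg adjustment over 9 tests, which did not pass. The share in SOS2 was lower than in the other baits with an exact permutation p = 0.0476 (adjusted p = 0.143). Genes with at least 10 reads numbered 2945 ± 723 in PKS5, 2480 ± 858 in SCAB1 and 3689 ± 1026 in SOS2 and no difference passed (exact permutation p = 0.238 to 1.0). At 0, 2 and 4 h the SOS2 library had 1469, 1115 and 346.5 genes more than the mean of the other 2, SCAB1 differed by -641.5, -539.5 and -1330.5, and PKS5 by -827.5, -575.5 and 984. With baits permuted within recovery times, in 27 arrangements that cannot give less than 0.037, the exact p for these was 0.0741 in SOS2, 0.222 in SCAB1 and 0.852 in PKS5. By the same test the share in PKS5 and the effective number in SOS2 had an exact p of 0.037, and none of 9 passed after adjustment (smallest adjusted p = 0.133). With at least 100 reads for detection, SOS2 had 522.2 genes more than the other baits (exact permutation p = 0.0238, not adjusted).

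Recovery time was compared across baits, with 1 library per bait and time. Genes with at least 10 reads were fewer at 2 h than at 0 h in all 3 baits, with differences of -1222 in PKS5, -1322 in SCAB1 and -1626 in SOS2, a mean difference of -1390 ± 210.4 (SD, n = 3). At 4 h they were fewer in SCAB1 and SOS2, with differences of -1609 and -1898, and the difference in PKS5 was 58. The share of the 10 highest genes was above that at 0 h in all 3 baits at 2 h, by 9.91 ± 4.85 percentage points, and the effective number differed by -85.4 ± 82.0. At 4 h these differences were 4.46 ± 4.98 and -68.2 ± 79.0. The effective number differed by -38.9 at 2 h without SOS2 replicate 1 or 2 and by -26.6 at 4 h without SOS2 replicate 1 or 3, when the share differed by 2.85. Without PKS5 replicate 1 or 3 these differences at 4 h were -105 and 7.33. For each measure, with 3 pairs the exact sign-flip permutation test cannot go below 0.25, which was its value at 2 h, and 0.5 at 4 h (adjusted p = 0.5 for each, over 6 tests). For single genes limma-voom with bait as a block called 0 genes for 2 h against 0 h (303 at an unadjusted p under 0.05) and 0 for 4 h (531), and limma-trend also called 0 for each. Under other filters and scalings up to 8 genes passed at 2 h and 12 at 4 h. The 2 counts depended on single libraries too. At 4 h, 25 genes passed without PKS5 replicate 3 and 4 without PKS5 replicate 2. At 2 h, 13 passed without SOS2 replicate 3, 10 without PKS5 replicate 3 and 1 without PKS5 replicate 2. These fold changes are relative to the TMM scaling, and for library size alone 97.3% of genes were lower at 2 h (median log2 difference -1.35) and 91.5% at 4 h (-1.04).

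**Figure D3:**
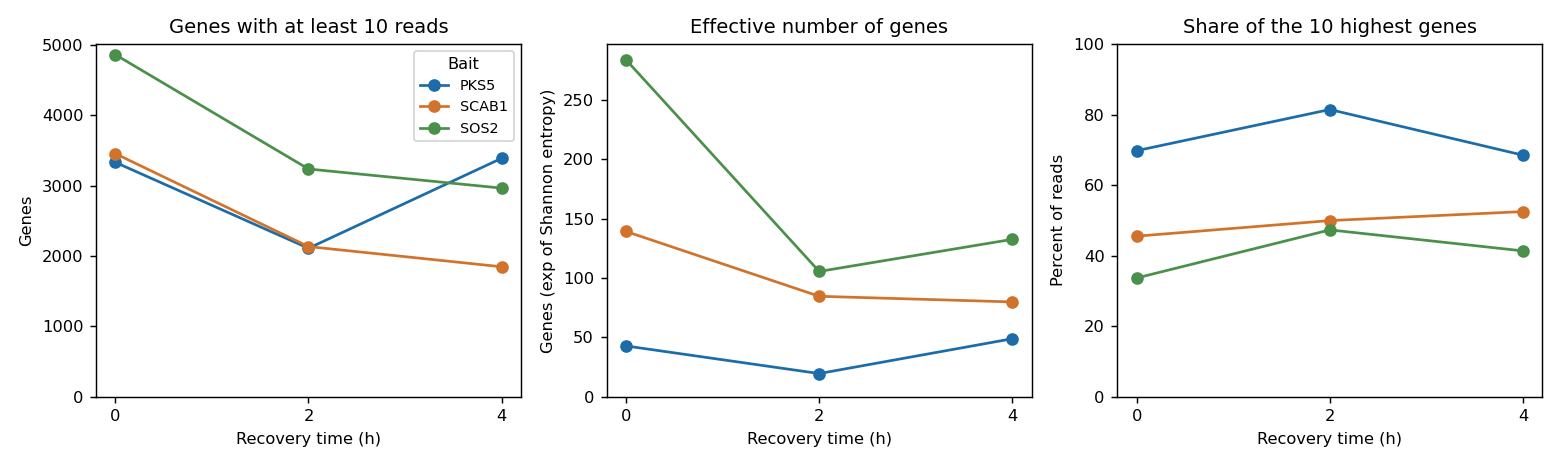
The panels give genes with at least 10 reads, the effective number of genes and the percent of reads in the 10 highest genes against recovery time (h), with 1 point per library and lines joining libraries of a bait. Genes with at least 10 reads are fewer at 2 h than at 0 h in each bait, and at 4 h PKS5 is back at 3391 while SCAB1 is at 1848 and SOS2 at 2966.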

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

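The test of sequencing depth and both tests at 4 h were chosen after the result was seen, and the test without the 50 highest genes at 2 h was set out before its value was computed. In 3 measures PKS5 moved the opposite way to the other baits between 0 and 4 h, with 1 library per bait and time, so the difference itself was not tested. Genes with at least 10 reads differed by 58 in PKS5 (4 h minus 0 h), by -1609 in SCAB1 and by -1898 in SOS2. With all libraries thinned to the same total these were 36, -1332 and -2236. Without the 128 genes among the 50 highest of any library and with the rest thinned they were -11, -623 and -908. PKS5 thus changed little in each case, whatever the sign, and its difference from the other baits remained. The effective number of genes differed by 6.08 in PKS5, -59.4 in SCAB1 and -151.2 in SOS2. The share of the 10 highest genes differed by -1.27 percentage points in PKS5, 6.97 in SCAB1 and 7.68 in SOS2.

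Genes with at least 10 reads were fewer at 2 h than at 0 h in 3 of 3 baits. Sequencing depth alone is argued against, since with all libraries thinned to the same total the mean difference was -1457 ± 44.8 (SD, n = 3 baits) and all 3 baits stayed lower. A few genes taking most of the reads are argued against as the whole of it, since without the 128 genes that are among the 50 highest of any library, and with the rest thinned to 170681 reads, the difference was -539.7 ± 175 and again 3 of 3 baits were lower. Distinct reads were fewer at 2 h too. They numbered 31294 and 22024 at 0 and 2 h in PKS5, 37151 and 22616 in SCAB1 and 47817 and 42533 in SOS2. Thinning of reads does not equalize distinct reads, and whether they account for the difference was not tested. An effect of recovery time stays open, and with 1 library per bait and time it cannot be separated from other differences between these libraries. With 3 pairs the exact sign-flip permutation test above could not go below 0.25, its value here.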

How the results depend on the processing

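Limma-trend, the fit on distinct reads, the fit without the libraries at 0 h and the test of a fold above 2 were chosen after the data were seen, as were the count of genes by distinct reads and the permutation of baits within recovery times. DESeq2 was planned and not run, and edgeR was not used either. Counts of called genes within 1.5 times the values in the report are not listed. For library size alone, 679 genes passed for PKS5, 830 for SCAB1 and 3 for recovery 4 h, all 3 lower. For library size without genes above 5%, 575 passed for PKS5 and 12 for 4 h. These scalings move the median of all genes, from -0.139 to 0.469 for PKS5 and from -0.204 to -0.841 for SCAB1 without genes above 5%, and from 0.157 to 0.565 for SOS2 by library size. The share called higher moved from 21.7% to 39.3% for PKS5 and from 41.1% to 28.7% for SCAB1 without genes above 5%, and from 66.6% to 85.0% for SOS2 by library size. The median SD within baits (log2) was 0.80 with TMM and 0.60 by library size for the 128 highest genes, and 0.61 and 1.05 for all 3811, so TMM narrows low genes and widens the highest. With no filter 1 gene passed for 2 h and 11 for 4 h. With 100 reads in 3 libraries, which tests fewer genes, 808 passed for SCAB1, 992 for SOS2, 1054 for any bait, 8 for 2 h and 3 for 4 h. With distinct reads 205, 220, 316 and 303 passed for PKS5, SCAB1, SOS2 and PKS5 against SOS2, and 381 for any bait, and of the first 4 counts 159, 175, 242 and 228 were also called with all reads, 158, 172, 238 and 225 in the same direction. Without the 0 h libraries 890 passed for SCAB1. A fold above 2 left 533, 668, 837 and 794. For other changes the cause was not tested.

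Leaving out 1 library gave 0 to 13 genes for 2 h and 0 to 25 for 4 h. It moved the difference in genes with at least 10 reads between -387 and 277.3 for PKS5, -1326 (without SCAB1 replicate 1) and -521 (without SCAB1 replicate 3, and -528 without SOS2 replicate 1) for SCAB1, and 389.5 (without SOS2 replicate 1) and 1338.5 for SOS2, and the PKS5 difference in the effective number between -112 and -71.3. The effective number differed by -23.3 to 31.4 for SCAB1 (above 0 without SCAB1 replicate 2 or 3 or SOS2 replicate 1 or 3) and by 49.9 to 139 for SOS2. The share of the 10 highest genes differed by 24.1 to 30.5 percentage points for PKS5 and by -23.8 to -16.5 for SOS2, and 2 libraries against 6 cannot go below 0.05. Here and below, 0.05 is set against exact p-values that are not adjusted, and in the report no bait difference in these 3 measures passed after adjustment. The SOS2 share was below it only without SCAB1 replicate 1. Taking the 1 highest gene, the differences were 12.4 for PKS5 (no longer past 0.05), -17.7 for SCAB1 (now past it), 5.24 for SOS2 and -0.382 for 4 h, the last 2 reversed. With 100 reads for detection SOS2 had 522.2 genes more than the others, and with distinct reads 426.4, each now past 0.05. With baits permuted within recovery times, the differences in the effective number were no longer past 0.05 for PKS5 (-101, exact p = 0.0741) and now past it for SOS2 (105, exact p = 0.037), and that in the share for SOS2 was no longer past it (-20.5, exact p = 0.0741). Leaving out 1 library, the recovery differences ran from -116 to -38.9 (2 h) and -105 to -26.6 (4 h) in the effective number and from 8.05 to 12.7 and 2.85 to 7.33 in the share. Pairs of different baits shared 42.2% of the 200 highest genes against 29.8% of the 50 highest. The causes were not tested.

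Of 2348 values of 128 results for named genes over 19 alternatives, 2156 kept direction and call, 188 lost the call and 4 turned direction, all 4 with distinct reads, where PBC1 and PAE2 came to 0.22 for PKS5 and 0.20 for SCAB1, and the PKS5 gene and PRF3 to 0.10 and -0.25 for SOS2. No scaling turned the direction of a named gene that was called.

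The title numbers stand for recovery times. After TMM scaling, same-numbered libraries of different baits had deviations correlated at -0.0326 to 0.147 and others at -0.202 to 0.161. The own number was best in 6 of 18 combinations of a library and another bait, so no pairing by number was seen in these deviations. TMM takes out a shift shared by most genes, so this does not show that recovery time has no shared effect. From 0 to 2 h TMM factors fell from 1.39 to 0.438 in PKS5, 1.72 to 0.564 in SCAB1 and 2.40 to 1.08 in SOS2. With the replicate block 1181, 1510, 1660 and 1265 genes passed for PKS5, SCAB1, SOS2 and PKS5 against SOS2, 1820 for any bait, and 0 list and bait pairs.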

Other observations

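All tests of this part, the divisions of the libraries included, were set out only after the result was seen, and the 3 gene groups were chosen after their values were seen. Of 10 genes listed for the CAR family, C2-domain proteins of abscisic acid signalling, 4 were tested, and other C2-domain genes were not counted. AT5G37740, AT1G70790 and AT2G01540 were called higher in PKS5 by limma-voom, the last at 5349 ± 4382 CPM (SD, n = 3) against 784.6 ± 238 in SCAB1 and 273.9 ± 113 in SOS2 (adjusted p = 0.000111), and AT1G70810 was not (adjusted p = 0.465). By the same test AT5G37740 was also called higher in SOS2 (log2 difference 1.96, adjusted p = 0.019). That call was lost without SOS2 replicate 2 (adjusted p = 0.118) or 3 (adjusted p = 0.321) or SCAB1 replicate 1 (adjusted p = 0.0778). Without PKS5 replicate 1 the mean of AT2G01540 in PKS5 was 2824 CPM, and it was still called (adjusted p = 0.00123, range over leaving out each library 2.1e-05 to 0.00298). Of 6 SnRK1 subunit genes, 3 were tested and all 3 were higher in SOS2. Beside AKINBETA1 these were AKINBETA2, at 221.4 ± 56.9 CPM against 2.38 ± 2.39 in PKS5 and 0.552 ± 0.618 in SCAB1, and the catalytic subunit KIN10, at 83.0 ± 25.9 CPM against 3.81 ± 3.44 and 4.61 ± 1.74. A one-sided exact Fisher test of SnRK1 genes called higher in SOS2 gave p = 0.0199, or 0.0627 adjusted over 9 tests, which did not pass. GAPC1 and GAPC2 were the 2 tested glyceraldehyde-3-phosphate dehydrogenase genes, both higher in SCAB1 (exact Fisher p = 0.0209, adjusted 0.0627) and in SOS2, and lower in PKS5. Both groups were chosen after their values were seen, and GAPC1 and GAPC2 are close copies. These Fisher p-values therefore cannot decide whether a bait recovers either group more often than other genes. The SOS2 call of GAPC1 (log2 difference 2.21) was lost without SOS2 replicate 2 (adjusted p = 0.0644) or replicate 3 (log2 difference 1.41, adjusted p = 0.0976), in a range over leaving out each library of 0.00543 to 0.0976.

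For the CAR genes the one-sided exact Fisher test gave p = 0.000819 for PKS5, or 0.00737 adjusted, with 3 of 4 tested members higher against 229 of all 3811 genes. Since the family was picked from the leading PKS5 genes, that p cannot decide whether PKS5 recovers the family more often than other genes. Reads of AT1G70790 counted for AT5G37740 are argued against, because that explanation needs about the same ratio in every library and the ratio of the 2 genes varied 2380-fold over the 9 libraries. For AT2G01540 the ratio varied 5.61-fold, between the bounds set for the test, and shared reads and recovery of AT2G01540 itself cannot be told apart.

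Low reads were found for many genes in every library, and 1990 tested genes below 100 CPM on average were not called for any bait. They held 1.13% of the reads in PKS5 replicate 2 and 6.41% in SOS2 replicate 1, the lowest and highest shares. Reads carried over between libraries are argued against by the levels of strong preys. If each library received 1 share of every other library's reads, the strong preys of other baits limit that share to 0.00579 to 0.0408%, and it accounts for 0.149% of the median low gene's reads. Library members that persist without the bait may be a source of these reads, but no unselected library was analysed here and this was not tested.

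Other divisions of the 9 libraries into 3 sets of 3 were fitted in the same way, 100 in number with the real one. In 1 of 100 divisions, the real one, as many genes passed for PKS5 (1054, the highest other 955), SCAB1 (1342, 954), SOS2 (1552, 954) and any bait (1717, 799). Libraries grouped by bait thus differed in more genes than in the other divisions tried. These divisions mixed recovery times, and libraries of a bait are not said to come from separate cultures. The divisions therefore cannot tell an effect of the bait from chance differences between single screens. Divisions that kept the 3 libraries of 1 bait together were not excluded, so the highest other counts may carry a difference between baits. For PKS5 against SOS2, the 6 libraries allow 10 divisions, too few for a share under 0.05, and 1 gave as many genes (1217, the highest other 0). For recovery 2 h and 4 h the divisions are also too few, the real counts were 0, and 10 of 10 gave as many, with highest others of 0 and 1.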
